A study of Mus musculus with 6 samples.

How the data were processed

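RNA was measured in 6 libraries of mouse rod photoreceptors, 3 in each of 2 groups. Newborn retinas received plasmids by in vivo electroporation on postnatal day 0, and EGFP-positive cells were collected by flow sorting on postnatal day 10. The control plasmid carried a scrambled short hairpin RNA (shRNA) and the other plasmid an shRNA against Jun, each at 2.5 µg/µl in 0.4 µl. A vector with EGFP under the Nrl promoter, at 1.5 µg/µl, marked rods in both groups. Per the labels' protocols, full-length cDNA was made with a low-input SMART-seq kit and libraries with Nextera XT, and no step that marks strand is stated. Groups and replicate numbers were taken from the labels. Nothing in the labels says which animals or litters a library came from, so p-values measure the spread between these libraries, part of which may be technical.

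The authors deposited estimated counts per gene, estimated counts per transcript, and a normalised gene table. Trimmomatic 0.39, kallisto 0.44.0 and edgeR 3.28.1 are named in the submitters' processing notes, without role or order, and the genome build is not given in the sources used here. The deposited estimated counts were not whole numbers and were rounded before each count test. Gene and transcript tables had the same library totals, but only 6.62% of gene values with transcript sums over 50 counts lay within 1% of that sum. Gene counts are therefore not sums of the transcript counts, so gene and transcript values are not on 1 scale and counting intervals and floors are approximate. The third deposited table is named as CPM, yet its columns summed to between 1250540 and 2385210. It was handled as a signal relative to a scale set by the authors, in which each library's counts were divided by 1 factor. Of 52143 gene identifiers, 51336 were found in GENCODE vM21, and 98.2% of those had the same chromosome, start and end there, so coordinates given are the deposited ones and fit GRCm38. The deposited gene table also holds 771 genes on patch sequences, some of them copies of genes on the main chromosomes between which reads may be split. No sample column was left out (0 columns).

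Library totals were 46239300, 105801000 and 32150100 counts in the controls and 13211300, 13325500 and 13998400 in the libraries labelled Jun knockdown, to 6 digits, so depth and group were fully confounded. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on group alone, with Benjamini-Hochberg adjustment over 12815 tested genes and a threshold of 0.05. Each standard error was the log2 fold change divided by the square root of the F statistic. Levels are TMM-normalised CPM, given as mean ± SD with n = 3. The same test was run on 20706 transcripts. Gene lists, 30 in number, the rule for genes to be named and the alternatives were chosen before the data were examined. The 28 lists with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, and again with an estimated correlation and with fry. Members past the threshold were counted over all genes and adjusted over the list alone. In counts of genes or members, fell, rose and passed as lower or higher mean past the threshold. Other members may also be lower or higher. Exact permutation tests of 3 against 3 libraries were two-sided, with 0.1 as the smallest p they can give. Where every library of a group had 0 counts, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with its 95% Clopper-Pearson counting interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

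The rule for genes to be named took Jun, the 12 genes with the largest change in each direction among those past the threshold with at least 5 CPM in the higher group and no overlap between groups, the 4 members of each list with the smallest p, all tested AP-1 members, and a set of photoreceptor genes that included Nrl, Crx, Nr2e3, Gnat1 and Opn1sw. It also took the 3 transcripts with the smallest p in each direction whose gene did not pass. Predicted gene models were counted and passed over. Malat1, Xist and the main-chromosome copy of Rab3a were added after their values were seen.

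The alternatives were other scalings (median of ratios, upper quartile, library totals), other filters, DESeq2 1.42.0, limma-voom with and without quality weights, a robust fit, limma-trend on the deposited signal with pseudocounts of 0.5 and 2, thinning to the smallest total, other thresholds, a replicate block, and leaving out each library. The functions were tested on simulated counts drawn from the real means, dispersions and library sizes of this comparison, with 200 changed genes. Among 12132 simulated genes, edgeR's test recovered 0% of genes changed by 1 on the log2 scale, 2% at 2, 18% at 4 and 75.5% at 8, and 4.08% of its 49 calls were unchanged genes. DESeq2, run on 12105 simulated genes, recovered 86% of genes changed by 8, but 70.2% of its 225 calls were unchanged genes. For limma-voom on 12132 simulated genes, 10% of 20 calls were unchanged genes. A gene that did not pass is therefore not shown to be unchanged.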

Results

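Rods purified from the mouse retina on postnatal day 10 were profiled by RNA sequencing after electroporation with a scrambled control or a Jun shRNA plasmid, with 3 libraries per group. The comparison asks which genes depend on Jun, a bZIP transcription factor of the AP-1 family, in early rod differentiation. Control libraries held 61396700 ± 39095000 counts and the libraries labelled Jun knockdown 13511700 ± 425320 (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Libraries correlated with Spearman coefficients of 0.613 to 0.757 within a group and 0.508 to 0.559 between groups. The first principal component held 35.3% of the variance and separated the groups.

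Jun (ENSMUSG00000052684, chromosome 4, 95049034 to 95052222, GRCm38) was not lower in the libraries labelled Jun knockdown. It stood at 6.50 ± 0.655 CPM in controls (n = 3) and at 1.84, 17.6 and 19.3 CPM in the labelled libraries, lower in 1 of 3. The log2 fold change was 0.99 (SE 1.44, adjusted p = 0.764, edgeR), and an exact permutation test gave p = 1. These data therefore do not show the knockdown at the RNA level, and each direction given contrasts libraries by label. With this SE a lower level is not excluded. RNA on postnatal day 10 also does not show Jun on earlier days or its protein. Where Jun is called not lower below, the group mean of its RNA on that day is meant. Of 11 tested AP-1 members 0 passed, 0 at an unadjusted p under 0.05, 0 adjusted over the list alone, and 0 with limma-voom (list median 0.65, camera adjusted p = 0.933). With DESeq2 0 of the 18 members with counts passed. DESeq2 gave an adjusted p to only 15502 of 33087 genes with counts, so some of these 18 may have had none. Fos, an immediate early AP-1 partner of Jun, stood at 70.9 ± 89.6 CPM in controls and 161 ± 58.4 CPM in the labelled libraries (n = 3 each, adjusted p = 0.668). Atf3, a stress-induced member, stood at 51.6 ± 22.6 and 5.76 ± 9.23 CPM (adjusted p = 0.375). Junb differed by 0.17 on the log2 scale (SE 1.67).

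**Figure D1:**
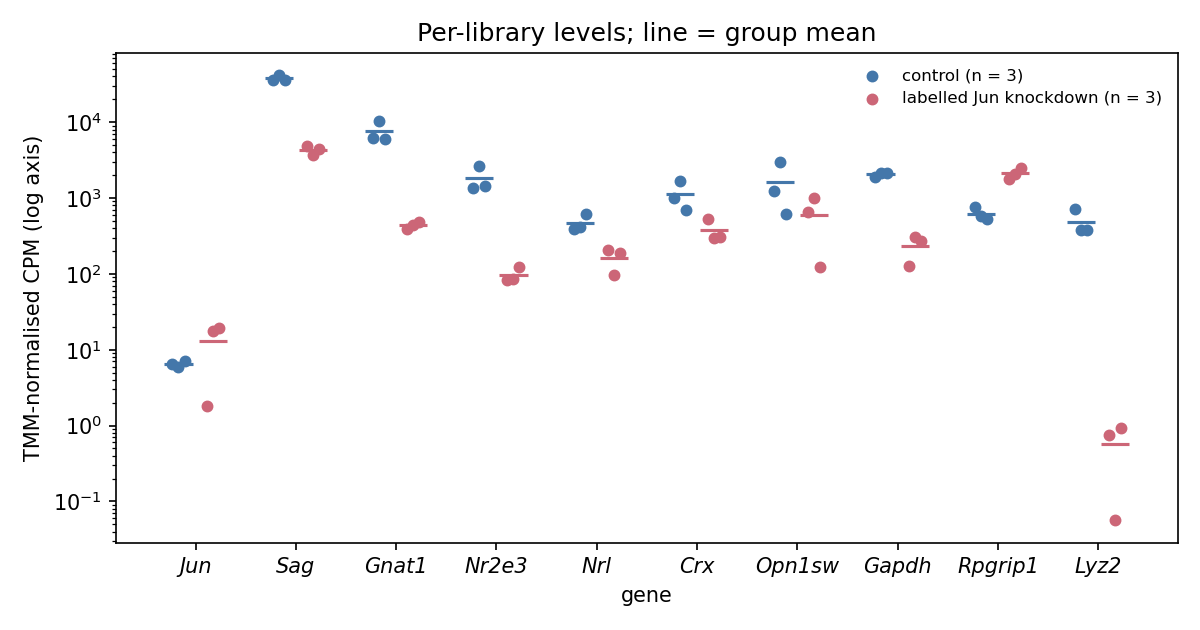
TMM-normalised CPM on a log axis for 10 genes, with 1 point per library and a line at each group mean (n = 3). Jun overlapped between groups, whereas Sag lay at 37806 CPM on average in controls and 4333 CPM in the libraries labelled Jun knockdown.

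Rod phototransduction genes were lower in the libraries labelled Jun knockdown, in which Jun itself was not lower. Sag, which encodes arrestin (ENSMUSG00000056055, chromosome 1, 87803680 to 87845158), fell by 3.13 on the log2 scale (SE 0.15, adjusted p = 7.06e-05), from 37806 ± 3252 to 4333 ± 593 CPM (n = 3 each). The log2 fold change was -4.11 (SE 0.29) for Gnat1, the rod transducin alpha subunit, and -2.34 (SE 0.22) for Pdc, which encodes phosducin. Of 26 tested members 10 passed as lower, 12 adjusted over the list alone, and 0 passed as higher, 1 adjusted over the list alone. In all, 20 members were negative and 6 positive, with a list median of -1.68 (camera adjusted p = 9.1e-05). With an estimated correlation the list gave adjusted p = 0.187. The disc protein genes Rom1 and Prph2 changed by -4.34 (SE 0.36) and -4.18 (SE 0.38), and Aipl1, a phosphodiesterase chaperone gene, by -4.18 (SE 0.45). Rpgrip1, a connecting cilium protein, rose by 1.76 (SE 0.28, adjusted p = 0.0199) in the outer segment and cilium list, where 4 of 30 members fell, 1 rose and the list did not pass (2 rose and 5 fell adjusted over the list alone, camera adjusted p = 0.22). With limma-voom the calls of Gnat1, Pdc and Prph2 ended (adjusted p = 0.332, 0.358 and 0.0950), and with DESeq2 those of Pdc (0.0524) and Rpgrip1 (0.131). The call of Rpgrip1 ended without control replicate 1, 2 or 3 (adjusted p up to 0.0898) and without knockdown replicate 2 or 3 (0.0508 and 0.0655). Depth and the retained-intron share, 8.48% against 3.23%, moved with the group as these genes did.

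Among photoreceptor transcription factors, Nr2e3, a nuclear receptor of rod identity, fell by 4.23 (SE 0.41, adjusted p = 0.00246) in the libraries labelled Jun knockdown. With limma-voom the call of Nr2e3 ended (adjusted p = 0.130). Nrl, the bZIP factor that specifies rods, stood at 473 ± 124 CPM in controls and 163 ± 58.1 CPM in the labelled libraries (log2 fold change -1.53, SE 0.46, adjusted p = 0.138, n = 3 each). Crx stood at 1124 ± 501 and 380 ± 135 CPM (adjusted p = 0.103), and Otx2 at 856 ± 255 and 227 ± 148 CPM (adjusted p = 0.115). Of 17 tested members 14 were negative and 1 passed as lower, 5 adjusted over the list alone (camera adjusted p = 0.0349, and 0.256 with an estimated correlation). In the ribbon synapse list Cplx4, a complexin gene, and Snap25, a vesicle fusion gene, changed by -3.09 (SE 0.38) and -1.42 (SE 0.20), 2 of 27 members in all (1 rose and 2 fell adjusted over the list alone), and the list did not pass (camera adjusted p = 0.721). Among cone genes Gnb3, the cone transducin beta subunit, fell by 2.63 (SE 0.51, adjusted p = 0.0444), 1 of 14 members (1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.933). Opn1sw, a cone pigment gene, stood at 1633 ± 1248 and 589 ± 437 CPM (adjusted p = 0.356). Leaving out any of the 6 libraries ended the call of Gnb3 (adjusted p 0.0840 to 0.159), leaving out control replicate 1 that of Cplx4 (0.0532), and leaving out control replicate 1 or 3 that of Snap25 (0.0597 and 0.0650). The call of Snap25 also ended with DESeq2 (0.264), upper quartile (0.0571) and library totals (0.0635, log2 fold change -0.92). That of Gnb3 also ended under each of the other 3 scalings, DESeq2 and limma-voom (0.0526 to 0.200). The list of transcription factors itself did not pass without control replicate 2 or 3 or knockdown replicate 1 or 2 (adjusted p 0.0539 to 0.0658). For these genes too, depth and the retained-intron share, 8.48% against 3.23%, moved with the group.

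Glycolysis genes were lower in the libraries labelled Jun knockdown, whose Jun level was not lower. The log2 fold change was -3.92 (SE 0.29, n = 3 each) for Ldha, lactate dehydrogenase A, -3.78 (SE 0.27) for Aldoa, an aldolase, -3.13 (SE 0.38) for Gapdh, a glyceraldehyde phosphate dehydrogenase, and -2.81 (SE 0.32) for Pgk1, a phosphoglycerate kinase. Of 22 tested members 9 fell, 12 adjusted over the list alone, with a list median of -2.91 (camera adjusted p = 2.0e-07; adjusted p = 0.185 with an estimated correlation). Nuclear genes of oxidative phosphorylation included Sdhd, Uqcrc1, Atp5b and Atp5a1, with log2 fold changes of -3.57, -4.67, -2.40 and -3.55, 4 of 41 members, 10 adjusted over the list alone (camera adjusted p = 0.0494; adjusted p = 0.840 with an estimated correlation). The median of that list was -0.38, and it turned positive under another scaling, up to 0.08. Uqcrc1 and Atp5a1 also have copies on patch sequences with the same levels, so their reads may be split and their values are uncertain. Hspa5, an endoplasmic reticulum chaperone, fell by 4.60 (SE 0.76), 1 of 20 members of the integrated stress and unfolded protein response list, 9 adjusted over the list alone (camera adjusted p = 0.000129; adjusted p = 0.185 with an estimated correlation). With limma-voom the calls of Ldha (adjusted p = 0.344), Hspa5 (0.105), Atp5a1 (0.137), Sdhd (0.0667) and Atp5b (0.0607) ended. Without control replicate 3 that of Gapdh ended (0.0564), and with library totals that of Atp5a1 (0.0575). Hspa5 passed only without knockdown replicate 3 (0.0202 to 0.118 over the 6 left-out libraries), and Atp5a1 only without knockdown replicate 2 (0.0407 to 0.129). Sdhd did not pass without control replicate 1 or 3 (0.0598 and 0.0619), Atp5b without control replicate 1 or 2 (0.0794 and 0.0660), or Uqcrc1 without any 1 control or knockdown replicate 3 (0.0629 to 0.0781). Oxidative phosphorylation as a list did not pass without control replicate 1 or 3 or knockdown replicate 2 or 3 (0.0508 to 0.280). Retained-intron share, 8.48% against 3.23%, and depth moved with the group here too.

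Among genes that passed the low-count filter, microglia, vascular, Müller glia and pigment epithelium markers were lower in the libraries labelled Jun knockdown, in which Jun was not lower, while the lists of amacrine, ganglion cell, cone, progenitor, astrocyte and bipolar markers did not pass (camera adjusted p 0.721 to 0.933). The microglia and macrophage markers Lyz2, which encodes lysozyme, and Ctss, cathepsin S, stood at 488 ± 191 and 154 ± 69.4 CPM in controls and at 0.574 ± 0.456 and 0.641 ± 0.131 CPM in the labelled libraries (n = 3 each). Of 16 tested members 5 fell, 12 adjusted over the list alone, with a median of -8.12 (camera adjusted p = 2.7e-12; adjusted p = 0.185 with an estimated correlation). For C1qb the counts were 8069 against 3, a ratio of 832 (95% interval 284 to 4033). Of 10 vascular and blood markers 3 passed as lower, 6 adjusted over the list alone (camera adjusted p = 0.000162, and 0.187 with an estimated correlation). They were Hbb-bs, a haemoglobin gene with 11966 counts against 3 (ratio 1233, 95% interval 422 to 5981), Rgs5, a pericyte marker with 4211 counts against 3 (ratio 434, 148 to 2105), and the haemoglobin gene Hba-a1, at least 1172-fold lower against the floor of 3 counts over the group, and the list median of -7.91 was the same with that gene at its bound. Over all 18 vascular and blood members the median was -0.83 without the filter and -0.67 with DESeq2. Hba-a1 and Hba-a2 are near-identical copies whose reads may be split, so both are uncertain. Müller glia markers had a median of -1.69 with 0 of 19 members past the threshold, 6 adjusted over the list alone and 6 at an unadjusted p under 0.05 (camera adjusted p = 0.00083, and 0.185 with an estimated correlation). With limma-voom 3 members passed, and with DESeq2 5 of the 20 with counts, not all of which need have had an adjusted p. Krt18, a keratin, fell by 9.13 (SE 1.03), 1 of 7 pigment epithelium markers, 3 adjusted over the list alone (camera adjusted p = 0.0349; adjusted p = 0.22 with an estimated correlation). The median of that list was -2.57, and over all 16 members it was -0.85 without the filter and -0.10 with DESeq2. Bipolar markers moved both ways, with Prkca higher by 3.76 (SE 0.76) and Sebox lower, at 109 ± 39.3 against 0.417 ± 0.0661 CPM, 1 of 17 each way over all genes and adjusted over the list alone. Leaving out any of the 6 libraries ended the calls of C1qb (adjusted p 0.0925 to 0.161), Rgs5 (0.0959 to 0.155), Hba-a1 (0.0531 to 0.142) and Prkca (0.0864 to 0.163), leaving out any 1 control or knockdown replicate 3 that of Hbb-bs (0.0711 to 0.118), leaving out control replicate 3 that of Ctss (0.0681), and leaving out any 1 control that of Sebox (0.0643 to 0.0963). The calls of C1qb and Rgs5 also ended under each of the other 3 scalings (0.0507 to 0.0614) and after thinning (0.0565 and 0.0566). The pigment epithelium list did not pass without knockdown replicate 1, 2 or 3 (0.141, 0.0551 and 0.0759). Retained-intron share, 8.48% against 3.23%, and depth moved with the group as these markers did.

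**Figure D2:**
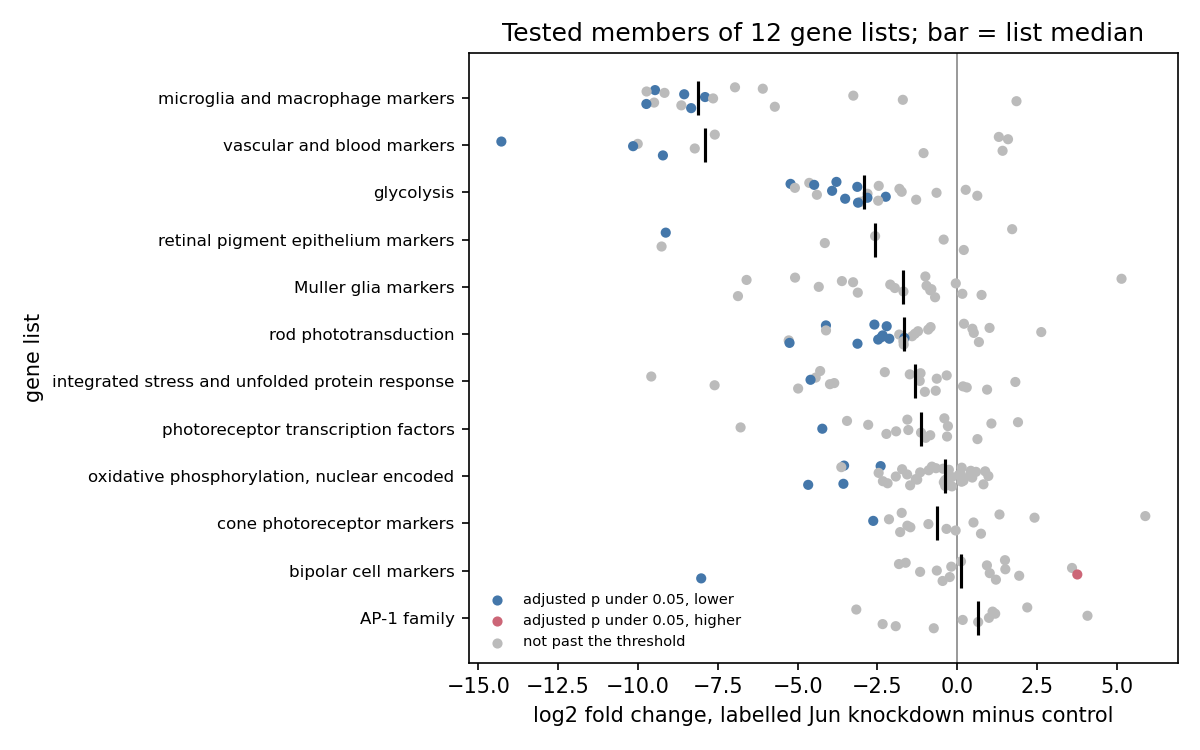
Log2 fold change (libraries labelled Jun knockdown minus control, n = 3 each) of each tested member of 12 gene lists, with a bar at the list median and colour for genes past an adjusted p of 0.05. Microglia and macrophage markers had a median of -8.12, rod phototransduction genes -1.68 and AP-1 members 0.65, and values of genes without counts in a group, such as Hba-a1, are fitted values and not bounds.

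Among genes higher in the libraries labelled Jun knockdown, where Jun was not lower, Grin2b, an NMDA receptor subunit gene, rose by 8.44 on the log2 scale (SE 0.86, adjusted p = 0.00341), from 0.884 ± 0.497 to 312 ± 140 CPM (n = 3 each). Tsix, the antisense transcript of Xist, was higher by 5.86 (SE 0.63). No strand marking is stated, so its reads may include those of Xist, which stood at 29.0 ± 16.0 and 320 ± 446 CPM. Tsix stood at 2394, 2426 and 2353 CPM in the labelled libraries, so it did not vary there as Xist did. The log2 fold change of Xist ranged from 1.09 to 4.04 with 1 library left out. The other largest rises were Parp14, Atad5, Zfhx4, Mir99ahg, Spopl and Ccdc36, from 5.87 to 10.31 on the log2 scale, and BC049715, Clec1b, Bloc1s6os and Hectd2os, with 1 or 2 counts in all controls together. Parp14 stood at 1.09, 358 and 199 CPM in labelled replicates 1, 2 and 3, and Atad5 at 2.38, 104 and 79.7 CPM. Both rises therefore rest mostly on replicates 2 and 3. With limma-voom the calls of Parp14 (adjusted p = 0.124) and Spopl (0.0507) ended. With limma-trend on the deposited signal plus 2 those of Parp14 (0.139), Atad5 (0.105) and Clec1b (0.0510) ended. For Clec1b the ratio was 3548 (95% interval 635 to 140268). The largest falls outside the lists above were Zfp784, at least 1636-fold lower, Rab3a on a patch sequence, at least 630-fold lower, and Moap1, Zfp420, Lyplal1 and Arpin. The copy of Rab3a on chromosome 8 stood at 187 ± 36.2 and 26.2 ± 12.3 CPM (adjusted p = 0.0770), so the patch value is uncertain. In all, 41 genes were higher and 173 lower, 214 of 12815 tested, each in 3 of 3 libraries, and Jun was not among them. At an unadjusted p under 0.05 there were 2159 genes, 28.3% of tested genes did not overlap between groups against 10% by chance, and all 214 calls were among these. Scaling by upper quartile gave 55 higher and 89 lower and library totals 68 and 79, with shifts of the median gene of 0.39 and 0.49, against 0.15 for median of ratios. Leaving out 1 control left 41, 57 and 36 calls for replicates 1, 2 and 3, and leaving out 1 knockdown library left 108, 110 and 104. Calls of the genes with the largest changes named here, other than Grin2b and Tsix, ended with any library left out, except Parp14 and Atad5 without knockdown replicate 1 (adjusted p = 0.00792 and 0.0303), Spopl and Ccdc36 without knockdown replicate 2 (0.0453 and 0.0476) and Moap1 without knockdown replicate 1 (0.0443). Over the left-out libraries adjusted p otherwise reached 0.184 for Hectd2os and Bloc1s6os. Of 53 named genes that passed, 16 still passed without each library in turn, and 11 passed under all 19 alternatives, among them Sag, Aldoa, Lyz2, Grin2b and Tsix.

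Long noncoding genes and retained-intron transcripts took larger shares in the libraries labelled Jun knockdown, where Jun was not lower. Long noncoding genes held 5.88 ± 0.714% of counts there and 2.28 ± 0.190% in controls, and retained-intron transcripts 8.48 ± 0.990% and 3.23 ± 0.405% of counts of protein-coding genes (SD, n = 3, exact permutation p = 0.1 each, the smallest possible). Malat1, a nuclear noncoding RNA, stood at 14973 ± 3019 CPM there and 5245 ± 1108 CPM in controls (log2 fold change 1.51, SE 0.21, adjusted p = 0.0117). Its call ended without control replicate 3 (adjusted p = 0.0660) and with DESeq2 (0.222). Of 1419 tested long noncoding genes 11 rose and 2 fell, with a median of 1.04, and of 10790 protein-coding genes 27 rose and 169 fell, with a median of -0.32 (Fisher's exact test on the calls, odds ratio 33.5, p = 1.1e-07, across genes, which are not independent). Mitochondrial genes held 3.37 ± 0.422% there and 4.34 ± 1.60% in controls (exact permutation p = 0.4).

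**Figure D3:**
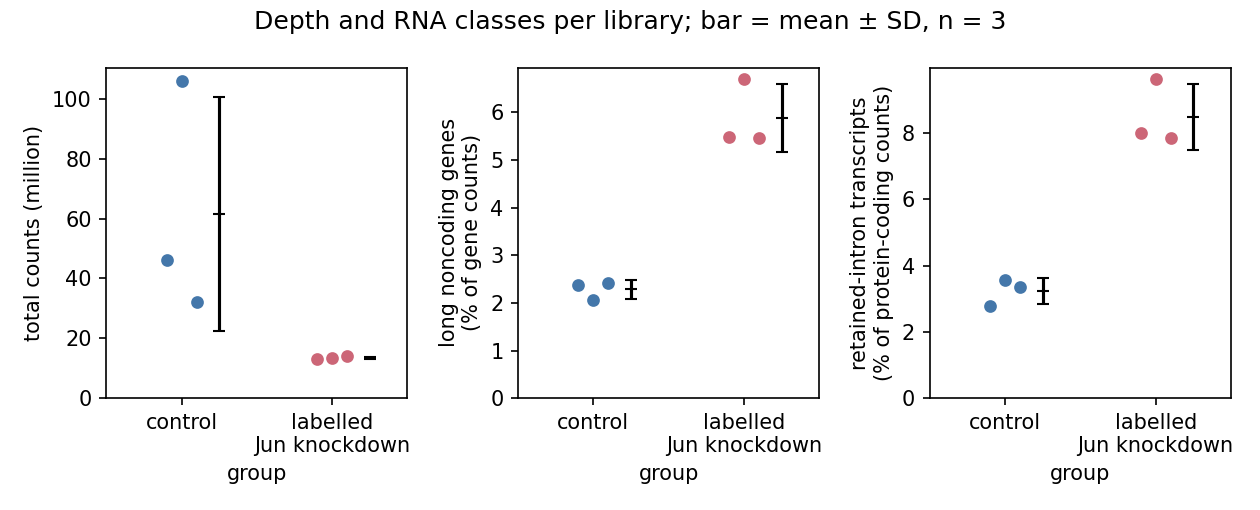
Total counts, long noncoding genes as percent of gene counts, and retained-intron transcripts as percent of protein-coding counts, with 1 point per library and mean ± SD beside them (n = 3). The libraries labelled Jun knockdown lay at up to 13998400 counts and 7.84 to 9.63% retained-intron counts, against at least 32150100 counts and 2.78 to 3.56% in controls.

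In the libraries labelled Jun knockdown, where Jun was not lower, retained-intron forms of Eif4a1, a translation initiation factor, and Hnrnpa2b1, an RNA-binding protein, rose by 8.19 (SE 0.93) and 3.68 (SE 0.47), whereas the genes themselves changed by -1.44 and 1.15 and did not pass. The Nxnl1-202 transcript of Nxnl1, which encodes rod-derived cone viability factor, fell by 6.05 (SE 0.54), from 598 ± 158 to 9.03 ± 2.20 CPM (n = 3 each), and Arl6ip1-201 fell by 3.11 (SE 0.33). Tmem30a-202 was at 0 in all controls and at least 7786-fold higher, and Morf4l2-202 was at 0 in all labelled libraries and at least 4231-fold lower. Of 20706 tested transcripts 12 were higher and 125 lower, and 38 of these 137 belonged to genes that did not pass. Of 3200 tested retained-intron transcripts 3 were higher and 2 lower. Deposited gene counts are not sums of transcript counts, which limits comparing a gene with its transcripts. Estimated counts carry an uncertainty of assignment between transcripts that these tests leave out. Leaving out 1 control left 19 to 22 transcripts lower and 1 to 3 higher, and leaving out 1 knockdown library 64 to 95 lower and 3 to 6 higher.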

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

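Jun stayed above 0 on the log2 scale and did not pass under any of 19 alternatives, from 0.23 to 1.52. The counts of higher and lower genes, 41 and 173 in the main test, were 19 and 78 with a replicate block, 38 and 125 with median of ratios, 55 and 89 with upper quartile, 68 and 79 with library totals, 164 and 573 without a filter, 110 and 241 with at least 5 CPM in 3 libraries, 855 and 1144 with DESeq2, 127 and 315 with limma-voom, 134 and 442 with quality weights, 38 and 167 with a robust fit, 103 and 512 with the deposited signal plus 0.5, 78 and 475 plus 2, and 43 and 104 after thinning. At adjusted p of 0.1 they were 182 and 462, and at 0.01 they were 4 and 34. Leaving out 1 library gave 5 to 17 higher and 31 to 95 lower, with fewer samples in each fit. In simulation, with 200 changed genes, 158 of DESeq2's 225 calls were false, a share of 70.2%. That share depends on how many genes truly change, so it cannot be applied to DESeq2's larger count here. For all settings the cause of the differences in count was not tested. Of the 53 named genes that passed, 0 changed sign under these alternatives, but calls ended for 25 with the block, 15 with limma-voom, 12 with quality weights, 14 after thinning, 12 with library totals, 11 with upper quartile, 7 each with median of ratios, DESeq2 and the robust fit, 2 and 5 with the deposited signal plus 0.5 and 2, and 22 to 35 with 1 library left out. The limma-voom losses included Gnat1, Ldha, Nr2e3, Pdc and Prph2. The labels do not say that equal replicate numbers pair the libraries. Same-numbered libraries had deviation correlations of 0.00042, 0.00804 and -0.0151, which do not show a pairing. With 3 libraries per group they cannot exclude one, so calls lost under the block are neither dismissed nor read as weaker effects. Of the 9 lists that passed, 0 passed with an estimated correlation in camera (6 at an unadjusted p under 0.05) and 9 with fry. The estimated-correlation adjusted p was 0.185 for microglia, glycolysis, Müller glia and the integrated stress list, 0.187 for rod phototransduction and vascular and blood markers, 0.22 for pigment epithelium, 0.256 for photoreceptor transcription factors and 0.840 for oxidative phosphorylation. The block gave 0.0537 for both photoreceptor transcription factors and pigment epithelium and 0.0781 for oxidative phosphorylation. The filter at 5 CPM gave 0.203 for photoreceptor transcription factors and 0.402 for oxidative phosphorylation, and median of ratios 0.0929 for the latter. With 1 library left out, photoreceptor transcription factors ranged from 0.0401 to 0.0658, pigment epithelium from 0.00439 to 0.141 and oxidative phosphorylation from 0.0133 to 0.280, while the other 6 lists stayed past the threshold. Mitochondrially encoded genes, which did not pass with all libraries, passed without control replicate 2 (0.0133). Transcripts higher and lower, 12 and 125, were 5 and 77 with the block and 136 and 949 without a filter, and 1 to 6 and 19 to 95 with 1 library left out. The libraries labelled Jun knockdown were the shallower ones throughout. In simulation with 200 changed genes, 3 libraries per group at this spread recovered only 18% of changes of 4 on the log2 scale. Recovery also depends on how many genes truly change, so that share need not hold for these data.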

Other observations

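Tests on the number of rods and of microglia among the sorted cells were chosen only after the results they bear on had been seen. Several lists that did not pass held members far apart between groups. Among immediate early genes, Zfp36, an mRNA-decay factor, stood at 27.4 ± 12.1 CPM in controls and 0.409 ± 0.477 CPM in the libraries labelled Jun knockdown (n = 3 each, edgeR adjusted p = 0.121), and 0 of 13 members passed, with 4 at an unadjusted p under 0.05 (camera adjusted p = 0.0906). With limma-voom 1 member passed, and with DESeq2 3 of the 25 with counts, not all of which need have had an adjusted p. The chaperone Hspa8 fell by 3.62 (SE 0.41, adjusted p = 0.00513), 1 of 13 heat shock genes, and mt-Co1 fell by 1.77 (SE 0.30), 1 of 13 mitochondrially encoded genes, a call that ended without control replicate 1 or 3 or knockdown replicate 1 or 2 (adjusted p 0.0610 to 0.118). The mt-Co1 call also ended with limma-voom (0.547), DESeq2 (0.198), upper quartile (0.0596), library totals (0.0518) and thinning (0.0612). Of 78 cytosolic ribosomal protein genes 46 were negative, and only Rplp0 passed as lower, by 2.07 (SE 0.40). Its call ended with any library left out (adjusted p 0.0778 to 0.161) and under each of the other 3 scalings (0.0617 to 0.0835). It also ended with DESeq2 (0.104), limma-voom (0.0521) and thinning (0.0703). The list median of -0.10 turned positive, up to 0.37, under other scalings. The 19 lists that did not pass had camera adjusted p from 0.0906 to 0.933, and 2 lists, horizontal cell markers and crystallins, had under 5 tested genes. Camera pointed up where the median or fry pointed down for retinal progenitor (median -0.30, up to 0.28 under other scalings), bipolar (fry down, median 0.12), rod chromatin (median -0.14, up to 0.31 under other scalings) and cell adhesion genes (fry down, mean -0.57, median 0.20). The medians of amacrine markers, -0.12, and retinal stress genes, -0.20, also turned positive under other scalings, up to 0.41 and 0.24.

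Rod phototransduction genes were lower in libraries whose mean Jun RNA on postnatal day 10 was not. Jun on earlier days and its protein are not shown by these data, so whether these genes depend on Jun stays undecided. After thinning to the smallest total 8 of the 10 called genes were still called lower, and 8 under each of the other 3 scalings. Most of these calls therefore did not need the larger totals of the controls or TMM scaling. Thinning keeps each gene's expected fold change, and the other scalings moved the median gene by only 0.15 to 0.49 on the log2 scale. Neither could undo falls of this size, so they do not decide on depth or scaling as a cause. Thinning does not equalise input or library preparation, which may have gone with depth and were not tested. The test for fewer rods among the cells assumed that other markers would rise alike. Medians of other cell type lists lay 8.23 apart on the log2 scale, from -8.12 for microglia to 0.12 for bipolar cells. Other cell types need not change alike, and the bound was set after the values were seen. A smaller share of rods therefore stays open. A shift of the whole RNA pool by expression level and length cannot be told apart, since the list median of -1.68 lay at the 0.01 percentile of 10000 matched lists when matched on all libraries and at the 7.63 percentile when matched on controls. The shRNA, and differences in sample handling between groups, stay open as untested.

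Long noncoding genes had a median of 1.04 in the libraries labelled Jun knockdown. The median of the 1147 still tested after thinning was 1.26, against 1.03 for the same genes before. Thinning keeps each gene's expected fold change, so this median could hardly have fallen and does not decide on read number. The median of all genes moved from -0.12 to 0.13. Thinning leaves differences in input and library preparation, which were not tested. Length alone is argued against: fold change rose with genomic span across protein-coding genes (Spearman coefficient 0.22 across 10650 genes, which are not independent), but the noncoding median stood at the 100 percentile of protein-coding lists matched on level and span. Retained-intron shares were 2.63 times as high in the labelled libraries and separated the groups, which is consistent with more unspliced or nuclear RNA in them, as a hypothesis. Whether that came from RNA quality, the sort or the shRNA was not tested, and group and depth were confounded.

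Microglia and macrophage genes were lower in a sort for Nrl-driven EGFP, which should remove such cells. The median of the 14 genes still tested after thinning was -8.15. Thinning keeps expected fold changes, so this median does not decide on read number. A pool shift is argued against by the 0 percentile among 10000 matched lists under both matchings. Input and library preparation, which thinning does not equalise, were not tested. Of 16 tested genes, 93.8% were below -1, with Lyz2 at 488 and Ctss at 154 CPM in controls, and 0 of them are in another list. This is consistent with a candidate explanation in which control sorts held more such cells or their RNA, although the bound was set after the values were seen.

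Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many genes (214, highest other 0), as many transcripts (137, highest other 0) and as many lists (9, highest other 5). The other splits had 310 to 469 genes and 377 to 677 transcripts at an unadjusted p under 0.05 in edgeR, and 0 genes past the threshold with limma-voom. With 10 splits a share under 0.05 cannot be reached. Every other split also mixes libraries of both labelled groups on each side, so a difference between those groups widens its spread. Few calls in the other splits are therefore no measure of chance.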
